A study of Mus musculus with 5 samples.

How the data were processed

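Samples were grouped by the times in the labels: 1 array of BALB/c bone-marrow-derived macrophages without LPS (0 h) and 1 array each after 0.5, 2, 7 and 21 h of LPS at 10 ug/ml. Each array compared macrophage RNA with RNA of day 17.5 C57BL6/J whole embryos. Per the labels, total RNA was extracted with a column kit, and cDNA was labelled through amino-allyl nucleotides, with Cy3 the only dye named. The authors deposited 1 signed log ratio per probe and array; background correction, normalization within arrays, filtering, the base of the logarithm and the direction of the ratio are not given in the sources used here.

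The deposited values ranged from -3.01 to 4.28 units. Column medians were 0.07 at 0 h, 0.13 at 0.5 h, 0.12 at 2 h, -0.01 at 7 h and 0.01 at 21 h, so the columns were close to centred but not centred exactly. The values alone did not settle the base, so the threshold for counting a gene, planned as 1 log2 unit, became 1 unit of the table, and no fold change was computed. The direction was taken as macrophage over embryo by a rule on 2 marker lists, of the macrophage lineage and of embryonic tissue. Some macrophage markers, Tlr2 and Fcgr1 among them, were higher after LPS. On the 0 h array, without LPS, the 2 list medians had the same order (0.15 against -0.62). Correlations between arrays over 18391 probes ran from 0.44 to 0.84, so no array ran opposite to another. Empty values numbered 209, 681, 255, 285 and 207 per array, in order of time. Signal over background was not used here, so dim spots could not be left out.

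Gene names came from the annotation of the array's probes. Of 19828 probes, 14759 had 1 gene, 170 had several and 4899 had none listed; only probes with 1 gene were named. Gene IDs of 14628 of these were found in a table of RefSeq genes, which changed 0 symbols. No coordinates are given, since the genome build behind the probe annotation is not given in the sources used here.

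In the main setting each array was centred on the median of the probes with a value on all 5 arrays, probes without a value on every array were left out, and the remaining 13876 named probes were averaged by gene, giving 8692 genes, 3034 of them with more than 1 probe. The change of a gene is its value at a time minus its value at 0 h, in which the reference RNA cancels. Since there was 1 array per time, genes were counted by size (a change of at least 1 unit) and no test was run. Measurement spread was the SD of the difference between 2 probes of a gene divided by the square root of 2, and members of a list were called above or below 2 SD when their change passed 2 times that spread.

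Before the data were examined, 23 gene lists, the threshold, the rule for named genes and most alternatives were fixed. A list was said to stand apart when its median lay at or above percentile 97.5, or at or below percentile 2.5, of 10000 random lists of the same size matched on the mean log ratio of the 5 arrays in 10 bins. This describes these arrays and is not a test. Because the mean of the 5 arrays includes those compared, percentiles of unmatched lists and of lists matched on the 3 other arrays were computed too, the latter chosen after the data were seen. Named genes were, per time, the 10 largest increases and 6 largest decreases, up to 4 members of each list with the largest absolute change, 17 genes followed over time where measured, and the 6 highest and 6 lowest ratios at 0 h. Genes whose probes disagreed in sign are given with their probes where they are described. A gene that 2 of these rules name counts under both, and not every gene the rule names is printed.

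Alternatives were values without centring, quantile normalization, cyclic loess, probes with a value on the 2 arrays compared, probes counted singly, a threshold of 1.5 units, leaving out genes in the lowest 10% of mean log ratio, and the 0.5 h array or the mean of the 0 h and 0.5 h arrays as baseline. Added after the data were seen were the removal of a running median over 201 probes along the probe numbers, genes with more than 1 probe only, and list percentiles under the running median and the 0.5 h baseline. Shared use of the 0 h array was simulated with unchanged genes carrying the measured probe spread, in 100 draws. The spread of a gene was drawn for all times together, so the simulation also carries probe effects common to several arrays. The number of genes that probe disagreement alone puts past 1 unit was drawn 100 times, with the noise divided by the square root of each gene's number of probes.

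The calculation was checked on simulated data with 200 of 8692 genes changed by 1.5 units and noise of single probes drawn from the probe differences, not averaged over the probes of a gene. It recovered 98.0%, 95.5%, 98.5% and 97.5% of the changed genes at 0.5, 2, 7 and 21 h, and 124, 209, 11 and 10 unchanged genes passed 1 unit. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and in R 4.3.3 with limma 3.58.1 for the quantile and cyclic loess normalizations.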

Results

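Total RNA from bone-marrow-derived macrophages of BALB/c mice was measured on 5 two-channel expression arrays, 1 for each time in a lipopolysaccharide (LPS) time course. The macrophages had been grown out of marrow in human CSF-1, the growth factor of the macrophage lineage. LPS is an outer-membrane component of Gram-negative bacteria that macrophages sense through Toll-like receptors, and here it came from S. minnesota and was given at 10 ug/ml. The 0 h culture received no LPS, and the other 4 had been in LPS for 0.5, 2, 7 and 21 h. No culture without LPS was measured at these later times. A change from 0 h therefore cannot be told apart from an effect of time in culture. RNA from day 17.5 whole embryos of C57BL6/J mice served as the common reference in the second channel. Each array had 19828 probes, of which 19147 to 19621 carried a value, and 8692 genes were measured on all 5 arrays. With 1 array per time there were no replicates, so the number of arrays limits the precision, and no difference between times has a replicate check or a p-value.

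The values were log ratios whose base is not given in the sources used here. Changes are therefore in units of the deposited log ratio, where 1 unit is 2-fold if the base is 2, 2.72-fold if it is e and 10-fold if it is 10. The direction of the ratio was not given either, and it was taken as macrophage over embryo, which is likely but not settled. On every array the macrophage-lineage genes (16 measured) had the higher median, from 0.13 to 0.50 units, and the embryonic-tissue genes (36 measured) the lower, from -0.62 to -0.36 units. If the ratio ran the other way, every "higher" would read "lower". The error that could be measured was the disagreement between probes of the same gene. Its SD in the change from 0 h (3034 genes) was 0.27 units at 0.5 h, 0.38 at 2 h, 0.23 at 7 h and 0.23 at 21 h. It covers spots and probes within these arrays, not cultures, animals or labelling. The SD of the changes of all genes was little different, at 0.29, 0.37, 0.25 and 0.25 units. Changes of 2 probes of the same gene correlated weakly, with r = 0.06, 0.10, 0.20 and 0.21 in order of time. Most of the spread of single-gene changes therefore cannot be told apart from this disagreement.

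Before LPS, the genes with the highest ratio to the embryo reference included those of a lysosomal protease and an interferon-inducible protein, and the lowest those of haemoglobin and albumin. The 6 genes with the highest ratio at 0 h were Mthfd2l (2.63), Ctss (1.76), Them7 (1.60), 1100001I12Rik (1.56), AW112010 (1.32) and Ifi204 (1.28). Ctss encodes the lysosomal protease cathepsin S, and Ifi204 is the interferon-inducible gene. The 6 lowest were Hbb-b1 (-1.93, 21 probes), Gas1 (-1.85), Alb (-1.75, 5 probes), Pitpnb (-1.69), Tmem45a (-1.68) and Rras (-1.68). Hbb-b1 encodes a haemoglobin chain and Alb serum albumin. Among the lists, the median ratio at 0 h was 0.38 for interferon-stimulated genes, 0.36 for MHC class I presentation and 0.21 for lysosomal genes. Markers of stromal cells had a median of -0.43, of neutrophils -0.20, of mast cells and platelets -0.15, of dendritic cells -0.04 and of lymphocytes 0.02. Mthfd2l was high on the 0 h array alone, with ratios from -0.17 to 0.15 on the 4 other arrays, and it rests on 1 probe.

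The 0.5 h array addressed the first response to LPS. Among immediate-early genes, Fos, a component of the AP-1 transcription factor, was higher by 0.76 units and Klf4 was at -0.56, both past 2 times the probe-to-probe SD. Gadd45b (0.51 units, 2 probes of 0.89 and 0.14) and Junb (0.48) lay within it. In the NF-kappaB list Nfkbia, the inhibitor that NF-kappaB induces, was higher by 0.63 units. The list of immediate-early genes (20 measured) did not stand apart as a group, with a median change of 0.09 units at percentile 94.98 of matched random lists; 1 member was above and 1 below 2 times the probe-to-probe SD, and 18 lay within it. Interferon-stimulated genes went both ways. Of the 26 measured, Oasl2 (-0.92 units, 2 probes of -0.92 and -0.91) and Rsad2 (-0.76) were below 2 SD, Irf1 (0.64), Igtp (0.60) and Ifi204 (0.57, named after its value was seen) were above, and 21 lay within. The median of -0.03 units lay at percentile 0.18 of matched but 13.9 of unmatched lists. MHC class II genes (8 measured) had a median of -0.12 units at percentile 0.46, with Ctss at -0.69 and H2-DMb2 at -0.28 units; 1 member was below 2 SD and 7 lay within. The embryonic-tissue list was at 0.05 units, at percentile 99.8 of matched and 84.0 of unmatched lists. Quantile normalization turned Ifi204 to -0.49 units and put Igtp at 0.22, Oasl2 at -1.41, Rsad2 at -1.21 and Ctss at -1.43, with a median of -0.14 for interferon-stimulated genes and 0.03 for embryonic tissue. In that setting Fos was at 0.52, under the 0.545 units that 2 SD made in the main setting. Without centring the medians were 0.03 for interferon-stimulated, -0.06 for MHC class II, 0.15 for immediate-early and 0.10 for embryonic-tissue genes. With the running median along the probe numbers removed, the interferon-stimulated median was -0.09.

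By size, 128 of 8692 genes were at least 1 unit higher at 0.5 h than at 0 h and 2 were lower. The largest increases were Cideb (3.56 units), Rwdd2a (3.24), Slc22a8 (3.22), Enkur (2.66), Mbd4 (2.62), Rnf19a (2.55), Spag6l (2.5), Tinf2 (2.48), Capsl (2.44) and Fes (2.42), each measured by 1 probe. The decreases were led by Mthfd2l (-2.48), Icam2 (-1.19), Oasl2 (-0.92), H2-Q8 (-0.90), Golt1b (-0.88) and Col22a1 (-0.86). Disagreement between probes alone, drawn 100 times, gave 55 to 97 genes past 1 unit in either direction where noise was averaged over a gene's probes, and 124 unchanged genes in 1 simulation with the noise of single probes, next to 130 observed. The drawn counts were not split by direction, here and at the later times, while the observed genes were 128 higher and 2 lower. These totals therefore do not show how much of the upward tail such disagreement makes. With quantile normalization 41 genes were higher and 13 lower, with Cideb at 2.77 units, and 213 of the 260 higher probes lay in probe numbers 1 to 6000, which hold 30.9% of all probes. Moved by more than 1.5 times in that setting were Rwdd2a (2.13), Enkur (1.66), Mbd4 (1.61), Rnf19a (1.54), Spag6l (1.45), Tinf2 (1.56), Capsl (1.35), Fes (1.38) and H2-Q8 (-1.36).

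**Figure D1:**
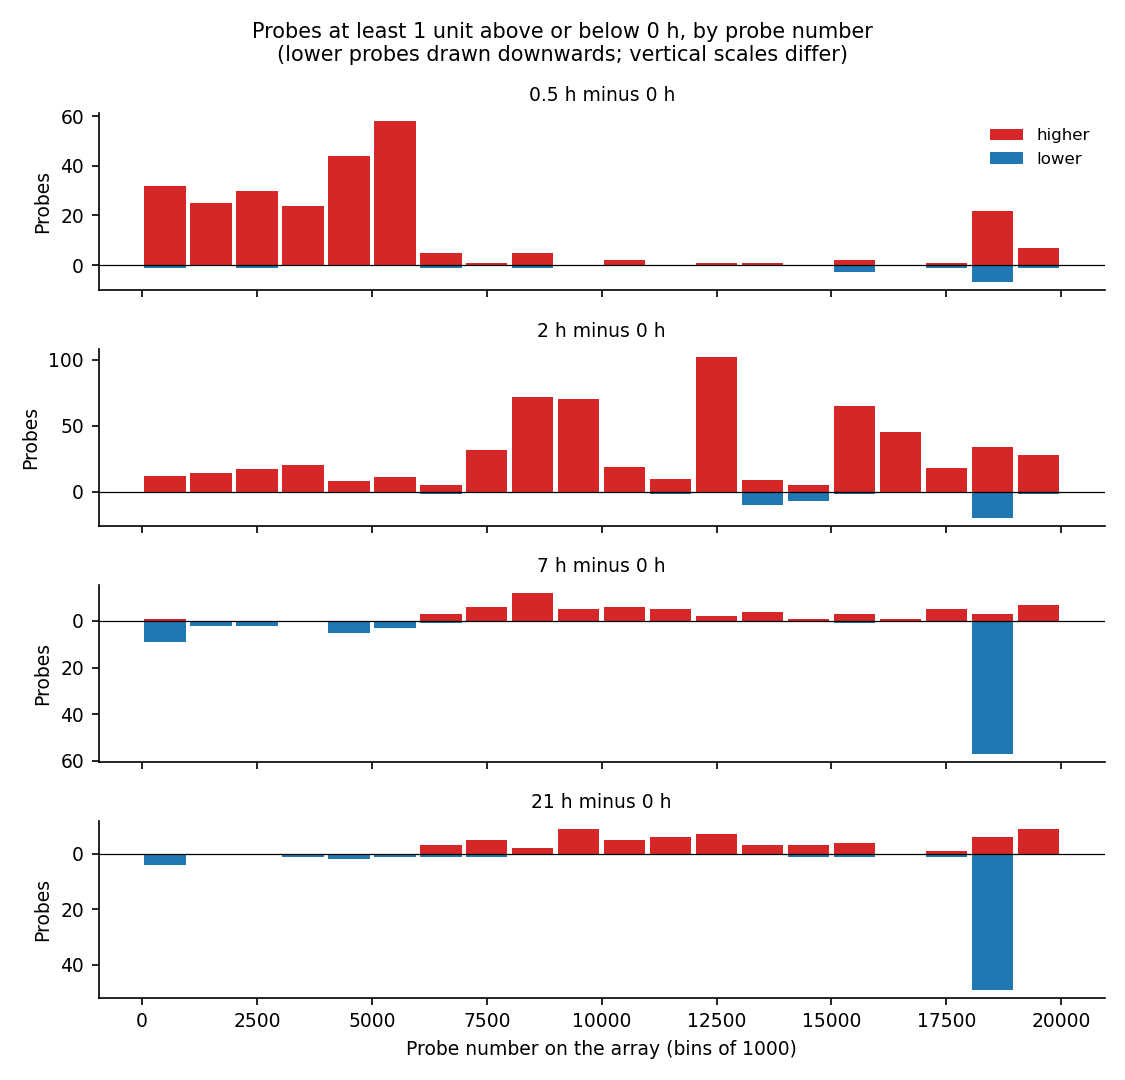
Number of probes at least 1 unit above (red) or below (blue, drawn downwards) the 0 h array in each stretch of 1000 probe numbers, for the 4 times in LPS, with 1 array per time. At 0.5 h, 213 of 260 higher probes lay in numbers 1 to 6000, and at 2 h 429 of 596 lay in 7001 to 17000. The latter numbers held 45 of 64 higher probes at 7 h and 44 of 63 at 21 h. At 7 h 57 of 80 lower probes lay in 1 stretch near the end of the array.

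At 2 h, single cytokine, interferon and NF-kappaB genes were higher than at 0 h, while most members of these lists lay within 2 SD. Il1a, which encodes interleukin-1 alpha, was higher by 1.21 units and its natural antagonist Il1rn by 0.76. The cytokine list named 27 genes, of which 8 were measured, and Tnf, Il1b and Il6 were not among the measured ones. Besides Il1a and Il1rn, the other 6 of the 8 lay within 2 SD, the growth factor gene Csf1 (0.73) among them. The list median of 0.12 units was at percentile 68.1 of matched and 81.2 of unmatched lists. The guanylate-binding protein gene Gbp2 was higher by 2.27 units, Eif2ak2 by 1.97 (2 probes of 1.25 and 2.70), Ifi204 by 0.97 and Irf1 by 0.83. The Eif2ak2 probe at 2.70 lay in probe numbers 12001 to 13000, the stretch of 1000 with most higher probes at 2 h (102 of 596). That probe was at 0.00 at 7 h and -0.04 at 21 h. In the NF-kappaB list (13 measured) the median was 0.34 units, with Map3k8 (1.12) above 2 SD and 12 within, among them Pim1 (0.63, 4 probes from -0.08 to 1.02). That median lay at percentile 68.3 of matched and 99.8 of unmatched lists, so its standing depended on the matching. The interferon-stimulated list had 6 members above 2 SD and 20 within, and its median of 0.12 units lay at percentile 1.75 of matched and 93.5 of unmatched lists; quantile normalization turned it to -0.10 units. Fcgr1, the high-affinity IgG receptor gene, was higher by 2.30 units, and the immunoproteasome gene Psmb9 by 1.0 (2 probes of 0.30 and 1.69). Pfkp, a phosphofructokinase gene, was higher by 1.56 units, Gins2 by 1.21 and Hexa by 1.01, and Nr1h3, which encodes the oxysterol receptor LXR alpha, was at -1.46 units. Quantile normalization lowered most of these values at 2 h: Gbp2 to 1.12, Eif2ak2 to 0.97, Il1a to 0.76, Fcgr1 to 0.70, Map3k8 to 0.64, Psmb9 to 0.12, Hexa to 0.21, Pfkp to 0.95, Gins2 to 0.65 and Csf1 to 0.48, and it turned Ifi204 to -0.31. The embryonic-tissue list was at 0.03 units, at percentile 99.1 of matched and 52.0 of unmatched lists, and lysosomal genes at -0.02, at percentile 0.65 and 20.8. Both small medians moved with the setting: embryonic tissue was at 0.10 with quantile normalization, 0.08 without centring, 0.01 with the running median removed and -0.02 with the 0.5 h array as baseline, and lysosomal genes were at -0.17, 0.04, -0.03 and 0.04. The NF-kappaB median was 0.12 with quantile normalization and 0.18 with the 0.5 h baseline, in which the cytokine median was 0.03 and the interferon-stimulated median 0.19.

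In all, 236 genes were at least 1 unit higher at 2 h and 8 were lower. The largest increases were Phactr4 (3.08 units), Pla2r1 (2.99), Ptger4 (2.97), Enpp5 (2.97), Dnase1 (2.86), Ccdc137 (2.75), Mecom (2.74), Abcb10 (2.72), Tmem18 (2.69) and Perm1 (2.65), each on 1 probe. Ptger4 encodes a prostaglandin E receptor. The decreases were led by Mthfd2l (-2.53), Lztr1 (-1.67), Nr1h3 (-1.46), Icam2 (-1.33), Nsun4 (-1.25) and Glipr2 (-1.15). Probe disagreement alone gave 140 to 192 genes past 1 unit in either direction, and the simulation with noise of single probes 209, next to 244 observed. Again these totals do not show how many of the 236 higher genes such disagreement makes. Quantile normalization gave 72 higher and 19 lower, with Dnase1 at 1.79, Mecom at 1.78, Ptger4 at 1.5 and Tmem18 at 1.35 units, cyclic loess 95 and 23, and the 0.5 h array as baseline 149 and 64. In that last setting Ccdc137 was at 1.82 units, Phactr4 at 1.44, Tmem18 at 1.05, Pfkp at 0.55, Ifi204 at 0.40, Pim1 at 0.26, Irf1 at 0.19, Lztr1 at -0.95, Icam2 at -0.14 and Mthfd2l at -0.05. The 2 h array was the widest of the 5, with an SD of its values of 0.55 against 0.32 to 0.43 on the others.

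At 7 h, the medians of the interferon-stimulated, NF-kappaB, MHC class I, cytokine and inducible effector lists lay above matched random lists, and that of the cell-cycle list lay below. Of 26 interferon-stimulated genes, 10 were above 2 SD, 1 was below and 15 lay within, with a median of 0.35 units at percentile 100 of matched lists. Among them Gbp2 was higher by 1.38 units, Usp18, a protease that limits interferon signalling, by 1.19, and the antiviral gene Rsad2 by 1.05 (2 probes of 0.94 and 1.17), while Ifi27l2a was at -0.90. The NF-kappaB list had the highest median, 0.56 units at percentile 100, with 7 of 13 members above 2 SD and 6 within. It was led by the kinase gene Pim1 (0.94 units, 4 probes from 0.82 to 1.02), Sod2 (0.81), Nfkbia (0.75) and Tlr2 (0.73). The 4 Pim1 probes were neighbours, in numbers 8115 to 8578. At 7 h probes of a gene at most 1000 numbers apart correlated at 0.26, and at 0.11 with the running median along the probe numbers removed. The 4 Sod2 probes disagreed in sign, from -0.04 to 1.42. MHC class I genes (11 measured) had a median of 0.37 units at percentile 99.96, with 4 above 2 SD and 7 within. Psmb10, an immunoproteasome subunit, was higher by 1.02 and the peptide transporter gene Tap2 by 0.67. Cytokines (8 of 27 measured) had a median of 0.27 units at percentile 99.9. Il1a at 1.99, Il1rn at 1.28 and Il18 at 0.66 were above 2 SD, and the other 5 lay within. Inducible effectors (17 measured) had a median of 0.20 units at percentile 99.9, with 3 above 2 SD and 14 within: Serpinb2 (1.23), the acute-phase gene Saa3 (0.79) and complement factor B, Cfb (0.70). Chemokines (11 of 23 measured) did not stand apart, with a median of 0.09 units at percentile 89.1, although Cxcl10 was higher by 1.28. With the 0.5 h array as baseline the percentile was 99.5. Ccl2, Ccl3, Ccl4, Cxcl1 and Cxcl2 were not measured, so this median does not speak for them. MHC class II genes did not stand apart either: all 8 lay within 2 SD, and the median of 0.02 units was at percentile 58.5, or 99.6 with the 0.5 h array as baseline.

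Cell-cycle genes (44 measured) had a median of -0.13 units at 7 h, at percentile 0.02, with 4 members below 2 SD, none above and 40 within. The lowest were Chek1 (-0.76 units), Anln (-0.72), Mcm4 (-0.62, 2 probes of -0.82 and -0.43) and Rfc4 (-0.52). Of the 44, 10 had positive changes, of which Nek2 (0.44 units) and Cdc20 (0.41), named after their values were seen, were the largest. Cholesterol efflux and lipid handling genes (13 measured) had a median of 0.24 units at percentile 99.5, with Nr1h3 (0.79) above 2 SD and 12 within. Lysosomal genes (29 measured) had a median of 0.11 units at percentile 98.4, led by Ctsc (0.62 units); 3 were above 2 SD, 1 below and 25 within. That call ended when the running median along the probe numbers was removed (percentile 96.0). Macrophage-lineage genes had 6 of 16 members above 2 SD, among them the Fc receptor gene Fcgr2b (0.86), Fcgr1 (0.76), Tlr2 (0.73) and Cd53 (0.65), and a median of 0.05 units at percentile 73.2. The embryonic-tissue list moved upwards too, by a median of 0.14 units at percentile 99.2, with Myh3 at 0.52 units, and this was 0.01 units at percentile 11.1 with the 0.5 h array as baseline and 0.08 at percentile 93.9 with the running median removed; it was 0.06 with quantile normalization. Among those that did not stand apart, the median was 0.03 units for immediate-early genes (percentile 68.8), in which Gadd45b was at 1.12 units (2 probes of 1.44 and 0.80). It was 0.10 units for internal reference genes (percentile 89.5). Without centring, medians at 7 h were -0.21 for cell cycle, 0.16 for cholesterol efflux, 0.12 for inducible effectors, 0.05 for embryonic tissue, 0.03 for lysosomal, 0.01 for chemokine, 0.02 for internal reference, -0.03 for macrophage-lineage and -0.06 for both immediate-early and MHC class II genes. With the running median removed, inducible effectors were at 0.11 and lysosomal genes at 0.07, and with the 0.5 h baseline lysosomal genes at 0.18, chemokines at 0.20, MHC class II genes at 0.21, macrophage-lineage genes at 0.09 and immediate-early genes at -0.04. Quantile normalization put Ctsc at 0.94 and Ifi27l2a at -1.35.

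By size, 24 genes were at least 1 unit higher at 7 h than at 0 h and 11 were lower. The largest increases were Phactr4 (2.16 units), Il1a (1.99), Slamf9 (1.54), Plpp7 (1.54), Siglecf (1.47), Gbp2 (1.38), the chemerin-binding receptor gene Ccrl2 (1.36), Abcb1a (1.32, 2 probes of 0.49 and 2.15), Cxcl10 (1.28) and Il1rn (1.28). The decreases were led by Mthfd2l (-2.81), Them7 (-1.33), 1100001I12Rik (-1.32), 1190028D05Rik (-1.26), Arhgap11a (-1.22) and Icam2 (-1.13). Probe disagreement alone gave 2 to 18 genes in either direction and the simulation 11, next to 35 observed. Without centring the split was 17 higher and 22 lower, with quantile normalization 50 and 52, with cyclic loess 20 and 21, and with the 0.5 h array as baseline 13 and 264. In that last setting Ccrl2 stood at -0.31, Plpp7 at -0.43 and Icam2 at 0.06 units, so the sign of these 3 turned. Smaller there were Phactr4 (0.51), Slamf9 (0.72), Siglecf (0.48), Abcb1a (0.50), Gadd45b (0.60), Pim1 (0.57), Serpinb2 (0.53), Nfkbia (0.12), Myh3 (0.29), Anln (-0.36), Mcm4 (-0.37) and Mthfd2l (-0.33), and larger were Rsad2 (1.82), Them7 (-2.16), 1100001I12Rik (-2.21), 1190028D05Rik (-2.58) and Arhgap11a (-2.33).

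**Figure D2:**
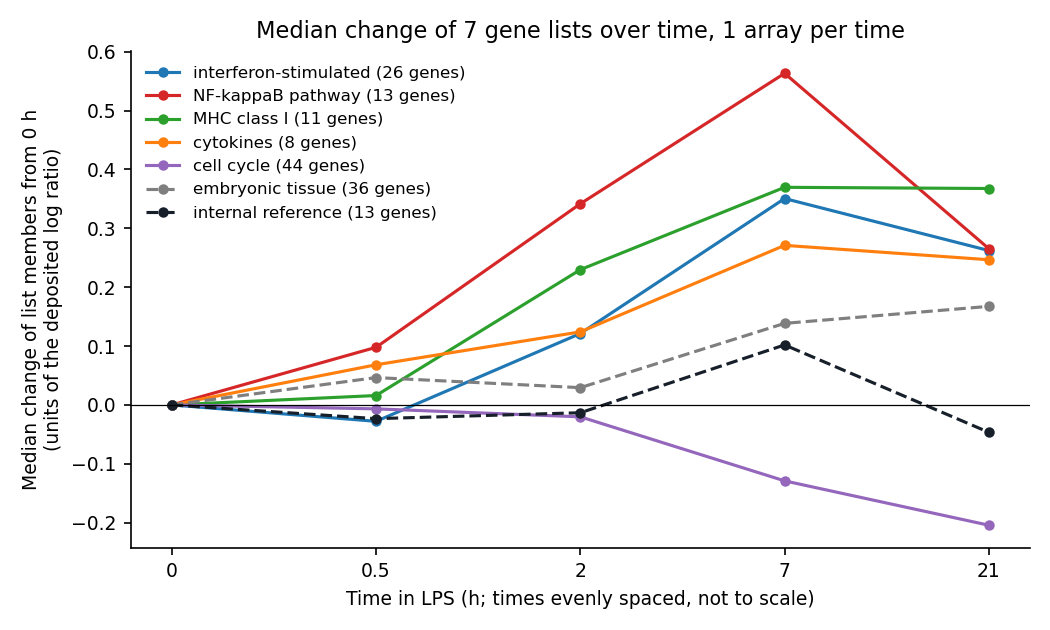
Median change from 0 h of the members of 7 gene lists against time in LPS, in units of the deposited log ratio, with 1 array per time. At 7 h the NF-kappaB list was at 0.56, MHC class I at 0.37 and interferon-stimulated genes at 0.35, while cell-cycle genes went to -0.20 at 21 h; the dashed lines are the embryonic-tissue and internal reference lists.

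At 21 h, the medians of the interferon-stimulated, MHC class I, cytokine and macrophage-lineage lists lay above matched random lists, and that of the cell-cycle list lay below. The interferon-stimulated list had 8 members above 2 SD, 1 below and 17 within, and its median was 0.26 units at percentile 99.3. It was led by Gbp2 (1.40 units), Rsad2 (0.93), Usp18 (0.82) and Ifi205 (0.77). MHC class I genes had a median of 0.37 units at percentile 99.6, with 2 above 2 SD, Tapbp (0.71) and Psme2 (0.55, 2 probes of 0.45 and 0.65), and 9 within. Cytokines had a median of 0.25 units at percentile 99.2, with Il1rn (1.03) and Il1a (0.93) above 2 SD and 6 within. The NF-kappaB list was at 0.27 units, at percentile 97.4 of matched and 99.96 of unmatched lists, with 3 above 2 SD, 1 below and 9 within. In it Pim1 was at 0.62 and Cflar at -0.53, the latter with 2 probes of -1.21 and 0.14. Macrophage-lineage genes had a median of 0.22 units at percentile 98.8, led by the tetraspanin gene Cd53 (0.80) and Fcgr1 (0.77), with 3 above 2 SD and 13 within; with the 0.5 h array as baseline the percentile was 97.4, just under the limit. Quantile normalization put Ifi205 at 1.18 and Tapbp at 1.10 units, and with the 0.5 h baseline the NF-kappaB median was 0.16.

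Cell-cycle genes had a median of -0.20 units at 21 h, lower than all 10000 matched lists. Of the 44, 7 were below 2 SD, none above and 37 within, and the lowest were the cytokinesis gene Anln (-0.76 units), the spindle gene Tpx2 (-0.71), the proliferation marker Mki67 (-0.67) and the replication helicase gene Mcm4 (-0.51, 2 probes of -0.62 and -0.41). The haem oxygenase gene Hmox1 was higher by 1.01 units and the peroxiredoxin gene Prdx1 by 0.54, with 7 of its 8 probes between 0.29 and 0.80 and 1 at -0.03. The oxidative stress list that holds them (20 measured) had 2 members above 2 SD and 18 within, with a median of 0.11 units at percentile 92.3. Inducible effectors had a median of 0.03 units at percentile 57.8, but 4 of 17 were above 2 SD, 1 below and 12 within: Saa3 (1.29), the arginase gene Arg1 (1.07), Serpinb2 (1.03) and Cfb (0.70) were the 4. With the running median removed the median was 0.11, at percentile 97.7. The embryonic-tissue list was at 0.17 units at percentile 99.9, with Dcx at 0.66 and Myh3 at 0.55, and it was at 0.07 units and percentile 47.2 with the 0.5 h array as baseline, 0.02 with quantile normalization and 0.11 without centring. Internal reference genes were at -0.05 units, at percentile 19.5.

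The other lists lay within the range of matched random lists at 21 h, but the standing of 4 of them depended on the setting. Medians were 0.12 units for chemokines (percentile 88.8), 0.16 for cholesterol efflux (92.6), 0.00 for cholesterol synthesis (15 measured, 48.5), 0.12 for glycolysis and hypoxia (15 measured, 95.1), and 0.04 for oxidative phosphorylation (27 measured, 83.4). They were 0.11 units for lysosomal genes (91.6), 0.05 for MHC class II (67.4) and 0.02 for immediate-early genes (58.7). In these lists Hif1a was at 0.61 units, with 5 of its 6 probes between 0.60 and 0.84 and 1 at -0.00, and the glucose transporter gene Slc2a1 at 0.47. The 5 Hif1a probes lay in numbers 8348 to 8638 and the other at 17471. Probes of a gene at most 1000 numbers apart correlated at 0.29 at 21 h, and at 0.13 with the running median removed. The agreement of these 5 neighbours is therefore weak support. With the 0.5 h array as baseline the percentile was 99.8 for chemokines, 99.9 for cholesterol efflux, 99.6 for lysosomal genes and 100 for glycolysis and hypoxia, with medians of 0.25, 0.28, 0.16 and 0.26 units. Unmatched lists put cholesterol efflux at 98.0 and lysosomal genes at 97.7. Sqle, the squalene epoxidase gene, was at -0.37 units, or 0.00 with the 0.5 h baseline, and Npc2 at 0.65. Markers of other cell types did not stand apart at any of the 4 times. At 21 h their medians were 0.01 units for neutrophils (7 measured), 0.17 for lymphocytes (7), -0.07 for dendritic cells (3), -0.01 for mast cells and platelets (5) and -0.06 for stromal cells (10). Without centring the medians of inducible effector, cholesterol synthesis, oxidative phosphorylation, MHC class II, immediate-early and neutrophil genes at 21 h were below 0, and several of these small medians moved by more than 1.5 times in other settings.

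By size, 22 genes were at least 1 unit higher at 21 h than at 0 h and 5 were lower. The largest increases were Phactr4 (2.05 units), Plpp7 (1.58), 1810009J06Rik (1.52), Siglecf (1.47), Gbp2 (1.40), Tmem45a (1.39), Chd9 (1.38), Fgl2 (1.38), Slamf9 (1.36) and Saa3 (1.29), each on 1 probe. The decreases were led by Mthfd2l (-2.78), Rnf113a2 (-1.91), Them7 (-1.49), 1100001I12Rik (-1.17), Icam2 (-1.11) and Arhgap11a (-0.93). Probe disagreement alone gave 3 to 19 genes in either direction and the simulation 10, next to 27 observed. Quantile normalization gave 49 higher and 36 lower, cyclic loess 16 and 13, and the 0.5 h array as baseline 14 and 233, where Plpp7 stood at -0.39 and Icam2 at 0.08 units. Smaller there were Phactr4 (0.41), Siglecf (0.47), Slamf9 (0.54), Chd9 (0.64), Tmem45a (0.56), Serpinb2 (0.33), Pim1 (0.25), Dcx (0.18), Myh3 (0.32), Anln (-0.40), Tpx2 (-0.29), Mcm4 (-0.26) and Mthfd2l (-0.30), and larger were Rsad2 (1.69), Cflar (-0.93), Them7 (-2.33), 1100001I12Rik (-2.06) and Arhgap11a (-2.03).

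**Figure D3:**
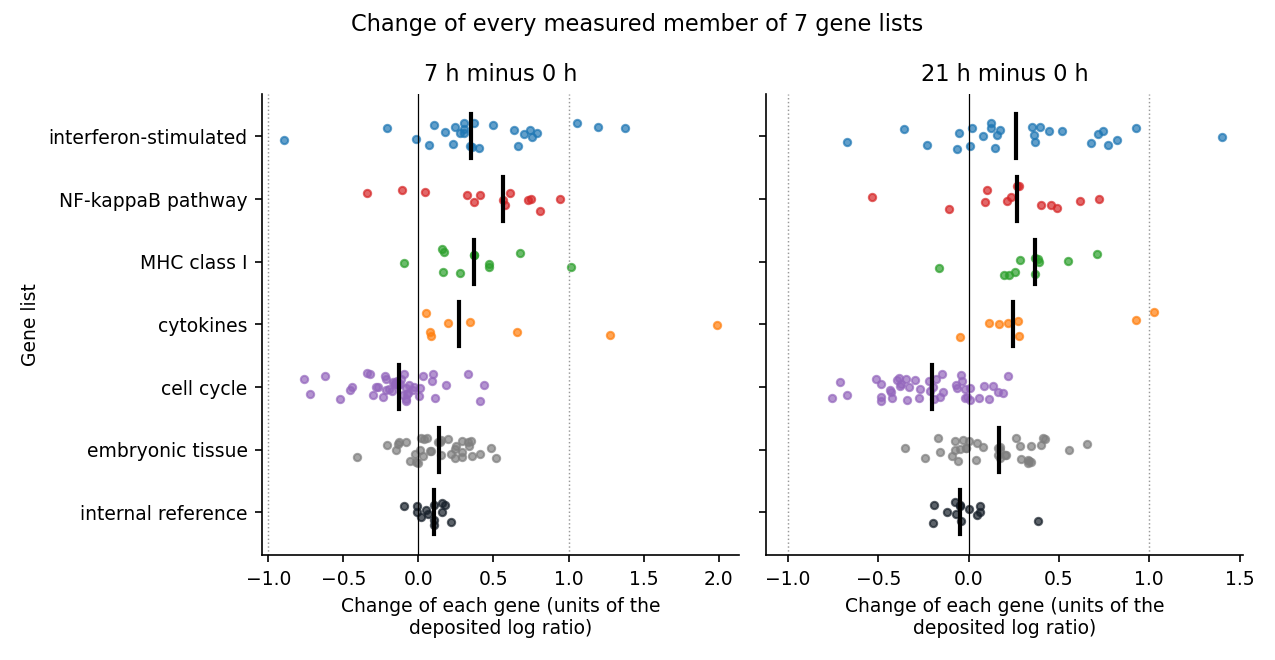
Change of every measured member of 7 gene lists at 7 h (left) and 21 h (right) from 0 h, in units of the deposited log ratio; each point is 1 gene, the black bar is the list median and dotted lines mark changes of 1 unit. Cell-cycle genes centre on -0.13 and -0.20, and interferon-stimulated genes on 0.35 and 0.26.

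Of the 17 genes whose time course was to be followed, 7 were measured. Tnf, Il1b, Il6, Il10, Il12b, Nos2, Egr1, Csf1r, Cd14 and Tlr4 were not. The chemokine gene Cxcl10 was at -0.11 units at 0.5 h, 0.57 at 2 h, 1.28 at 7 h and 0.90 at 21 h. Ifit1, an interferon-induced antiviral gene, went from -0.45 at 0.5 h to 0.45, 0.74 and 0.71, and its 2 probes had the same sign at every time. These probes were neighbours, in numbers 12305 and 12354, so their agreement is weak support. At 2 h they were at 0.05 and 0.86. Their lowest change at 7 h and 21 h was 0.68, or 0.45 with the running median along the probe numbers removed. Irf7, a transcription factor of the interferon response, was at 0.28, -0.02, 0.64 and 0.52 units, with probes of opposite sign at 2 h only. Fos was higher at 0.5 h alone (0.76 units), with -0.15, -0.10 and -0.16 afterwards. Nfkbia was at 0.63, 0.58, 0.75 and 0.46 units. For Ptgs2, the inducible cyclooxygenase gene, the 4 changes were -0.25, -0.31, 0.08 and -0.05 units, and for the chemokine gene Ccl5 -0.04, 0.04, -0.03 and 0.12, all within 2 SD. Quantile normalization turned Ifit1 at 2 h to -0.35 and put it at -0.81 at 0.5 h. Irf7 was then at 0.06, -0.33 and 0.97 at 0.5, 2 and 7 h, and Cxcl10 at -0.24, 0.07 and 1.36 at 0.5, 2 and 21 h. Fos was then at 0.52, -0.27 and -0.17 at 0.5, 2 and 7 h. Against the 0.5 h array, the changes at 2, 7 and 21 h were 0.90, 1.19 and 1.17 for Ifit1, -0.30, 0.36 and 0.24 for Irf7, -0.91, -0.86 and -0.92 for Fos, -0.05, 0.12 and -0.17 for Nfkbia, and -0.05, 0.33 and 0.21 for Ptgs2. Without centring Ccl5 at 0.5 h, Irf7 at 2 h and Ptgs2 at 7 h turned sign, and so did Ccl5 at 7 h against the 0.5 h array. Other moves of more than 1.5 times were of values within 0.2 units of 0.

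Of the 370 genes that were at least 1 unit from 0 h at any time, 120 had their largest change at 0.5 h, 215 at 2 h, 21 at 7 h and 14 at 21 h. The changes at 7 h and 21 h were alike across genes (Pearson r = 0.79, Spearman rho = 0.77 over 8692 genes, which are not independent replicates), and 10 genes were at least 1 unit higher at both, Phactr4 and Gbp2 among them. Unchanged arrays with the measured probe spread gave r = 0.76 and 1.64 such genes, and independent lists would share 0.0607. That spread was drawn for all times together. It thus carries both the shared 0 h array and any probe effect common to the 7 h and 21 h arrays, which this simulated r cannot separate. The covariance was 0.0507 against a simulated 0.0342. With separate baselines (0 h for one time and 0.5 h for the other) r was 0.58 and 0.49. The changes at 0.5 h and 2 h correlated with r = 0.49 (simulated 0.54), and those at 0.5 h and 7 h with r = -0.06 (simulated 0.10).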

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

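The removal of a running median along the probe numbers, the restriction to genes with more than 1 probe, the matching on the 3 other arrays, and the list percentiles under the running median and the 0.5 h baseline were chosen after the data were seen; the other settings were planned. No paired analysis was possible because each group has 1 sample, and no replicate could be left out. Signal over background was not used here, so its effect is unknown. Counts are given as higher and lower genes in order of time; in the main setting they were 128 and 2, 236 and 8, 24 and 11, and 22 and 5. Except where the way a setting is built gives the reason, the cause of a difference was not tested.

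By construction, a threshold of 1.5 units gave fewer genes (54 and 1, 81 and 2, 4 and 1, 3 and 2), probes counted singly gave more (198 and 6, 431 and 27, 46 and 19, 39 and 11), and the 3034 genes with more than 1 probe gave fewer (12 and 0, 39 and 1, 4 and 0, 1 and 0). Quantile normalization gave 41 and 13, 72 and 19, 50 and 52, and 49 and 36; it forces the 5 arrays to 1 distribution, so the wide 0.5 h and 2 h arrays lost higher genes and the 7 h and 21 h arrays gained them. All 41 and all 72 were among the 128 and 236. Cyclic loess gave 95 and 23 at 2 h, 21 lower at 7 h and 13 lower at 21 h, and its other 4 counts stayed within 1.5 times. Without centring 22 were lower at 7 h, and the other 7 counts stayed within 1.5 times. Probes with a value on the 2 arrays compared gave 34 lower at 7 h and 21 lower at 21 h. Leaving out the lowest 10% of log ratios gave 2 lower at 2 h. Removal of the running median gave 6 lower at 7 h, all among the 11.

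With the 0.5 h array as baseline there were 149 and 64 genes at 2 h, 13 and 264 at 7 h, and 14 and 233 at 21 h; 7 of the 13 and 7 of the 264 were called at 7 h in the main setting too. The mean of the 0 h and 0.5 h arrays gave 10 and 123 at 7 h and 8 and 90 at 21 h. Signs turned with the 0.5 h baseline for the embryonic-tissue median at 2 h (-0.0168), the lysosomal median at 2 h (0.0382), Ccrl2 at 7 h (-0.31), Icam2 at 7 h (0.0557) and 21 h (0.0767), and Plpp7 at 7 h (-0.43) and 21 h (-0.39). Without centring the interferon-stimulated median at 0.5 h became 0.0295 and the lysosomal median at 2 h 0.0367, and with quantile normalization the interferon-stimulated median at 2 h became -0.10. These were all the turned signs among medians of lists that stood apart, and among those of 410 values of genes named for their change at 1 time that were at least 1 unit from 0 h; the values of these genes at other times were not included. Smaller values turned as well: among them, quantile normalization turned Ifi204 at 0.5 h (-0.49) and 2 h (-0.31) and Ifit1 at 2 h (-0.35), and the 0.5 h baseline turned Mcm7 at 2 h (-0.11). Of 92 list percentiles, 9 changed their standing with unmatched lists, 7 with the running median removed and 0 with matching on the 3 other arrays; of 69 that could be computed with the 0.5 h baseline, 14 did. At 7 h the interferon-stimulated, NF-kappaB, MHC class I, cytokine, inducible effector, cholesterol efflux and cell-cycle lists kept their standing in all of these, and at 21 h the interferon-stimulated, MHC class I, cytokine and cell-cycle lists did. Of 410 values of named genes, quantile normalization moved 107 by more than the probe-to-probe SD and left 303 within it. The 0.5 h baseline, at 2, 7 and 21 h, moved 80, turned 5 and left 222 within it.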

Other observations

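The tests of explanations in this part were chosen after the results they concern had been seen, so each explanation is a hypothesis; quantile normalization and the 0.5 h baseline, which some of them use, had been planned as settings.

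Among the 3034 genes with more than 1 probe, 8 had every probe at least 0.5 units above 0 h at both 7 h and 21 h, and 0 had every probe as far below. They were Cfb, Ctsc, Fabp2, Ifit1, Pim1, Rsad2, Serp1 and Snx10; Fabp2, Serp1 and Snx10 are named here because of these values. Serp1 was at 1.06 and 0.73 units, Snx10 at 0.90 and 0.80, and Fabp2 at 0.59 and 0.94. Chance agreement of unrelated probes is unlikely to be the whole source, since 1000 shuffles of the genes over the probes gave at most 5 (mean 0.833). A shift shared by neighbouring probe numbers could have added to the count: with the running median removed 4 genes met the rule (at most 3 in 1000 shuffles), and of the 8 only Cfb, Rsad2 and Snx10 were among them.

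The first pattern is the long upward tail at 0.5 h and 2 h. If the RNA of most of these genes had been higher, their other probes would be higher too. The genes looked up had a probe at least 1 unit higher and another probe, whether or not their mean passed 1 unit. Of the 128 and 236 genes higher at 0.5 h and 2 h, 12 and 39 had more than 1 probe. Most of the tail is therefore not covered. At 0.5 h the other probes had a median change of -0.00102 units (81 genes, bootstrap -0.0216 to 0.0316). That lay below the 0.26 at 7 h (24 genes, 0.11 to 0.51) and 0.16 at 21 h (18 genes, 0.0964 to 0.31). It argues against higher RNA in most of the genes looked up at 0.5 h. At 2 h the question stays open. The median of 0.13 (216 genes, 0.0813 to 0.18) overlaps the value at 21 h. The share of genes looked up whose other probes had a median at least 0.5 units higher was 13.9% at 2 h, 33.3% at 7 h and 22.2% at 21 h. Among all single probes of genes with more than 1 probe, 10.1%, 3.33% and 4.86% were that high. The latter shares count single probes and include the selected ones. The 2 kinds of share are therefore unlike and do not decide the question. Single spots reading high in some stretches of probe numbers may be a source. The variance over the mean of higher probes per 1000 numbers was 21.2 at 0.5 h and 24.0 at 2 h, against at most 2.19 and 2.25 in shuffles. It passed its shuffles at 7 h (3.07 against 2.20) and 21 h (3.33 against 2.59) too. At equal crowding this ratio rises with the number of probes counted (260, 596, 64 and 63 in order of time). Its size therefore cannot be compared between times. Numbers 7001 to 17000, with 50.7% of all probes, held 72.0% of the higher probes at 2 h, 70.3% at 7 h and 69.8% at 21 h. Crowding was thus not particular to the 2 early times, but its place differed at 0.5 h. Numbers 1 to 6000, with 30.9% of all probes, held 81.9% of the higher probes at 0.5 h. At 2, 7 and 21 h they held 13.8%, 1.56% and 0%. Whether a wider spread of these arrays left by the normalization adds to it stays open: quantile normalization brought the counts to 41 and 72 genes, next to 50 at 7 h, but it gives the 5 arrays 1 distribution whatever the source of the tail.

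The second pattern is a stretch of 1000 probe numbers near the end of the array that held 57 of the 80 probes lower at 7 h and 49 of those lower at 21 h, 47 of them at both. The median ratio of the 57 was 1.31 at 0 h, 1.59 at 0.5 h, 0.94 at 2 h, -0.10 at 7 h and 0.05 at 21 h. The 0 h array alone is unlikely to be the cause, because 44 of the 57 stayed at least 1 unit lower with the 0.5 h array as baseline. Whether RNA of these genes was lower cannot be told apart from an effect of the spots: 0 of the 57 probes had a single gene listed, so no other probe of the same genes could be looked up.

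The third pattern is the likeness of the changes at 7 h and 21 h. The shared 0 h array alone is unlikely to explain it, as the correlation across genes with separate baselines was still 0.577 and 0.491. Probe effects common to the 7 h and 21 h arrays cannot be told apart from a lasting change in RNA. Differences between 2 probes of the same gene, which carry no change in RNA if both measure it equally, correlated at 0.456 and 0.375. A lasting change in RNA could itself come from LPS or from time in culture, since no later culture was without LPS. No slide batch or hybridization day is given in the sources used here, so the 3 earlier and 2 later arrays could not be compared within a batch.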
